A study of Arabidopsis thaliana with 4 samples.

How the data were processed

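RNA was measured in shoot apices from inflorescences of 6-week Arabidopsis thaliana plants, with older flowers taken off, in Col-0 (wild type, WT) and in a line carrying mutations in both MP and CLV3 (mp clv3). Per the labels' protocols, the plants grew in a greenhouse at 22°C, poly(A) RNA was purified from total RNA, strand-specific libraries were made with a NEBNext Ultra kit, and paired reads of 100 bases were taken on an Illumina HiSeq instrument. The labels give 2 biological replicates per genotype. The submitters' processing notes name CASAVA 1.7, BWA and the TAIR10 build, without saying what each was used for; whether counting used the strand and how reads with several matches were placed is not given in the sources used here.

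The deposited table holds 1 column of read numbers and 1 column of RPKM per genotype, with no replicate number. Whether a column sums the 2 replicates or holds 1 of them is not stated. The read numbers deposited by the authors are handled as estimated counts: they are whole numbers, except that 0 is written as 0.5, which was set back to 0 here. The RPKM values deposited by the authors are these read numbers scaled by the length of the gene model and by the total of reads. A single total per genotype turns every model's RPKM into a whole-number length (median 1326 bases). The log2 ratio deposited by the authors equals the log2 of the ratio of the RPKM columns. The FDR, an adjusted p-value column in the authors' deposited table, comes from a test that is not stated. Of the 27323 gene models, 1 was left out because its cells are shifted against the header, which left 27322.

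The models held 103347441 reads in mp clv3 and 101878433 in WT. Models with 2 reads were far more frequent than models with 1 or 3 (717 against 99 and 88 in mp clv3, 744 against 105 and 75 in WT), as when both mates of a pair are counted. Intervals were therefore computed on read pairs, taken as the read number divided by 2 and rounded up. Each ratio was taken from the read numbers divided by the genotype's total, with an exact (Clopper-Pearson) 95% interval. These intervals cover counting error only: they hold neither the spread between plants nor duplicate molecules from PCR, since no molecular identifiers are described. For a model with 0 reads in a genotype, the floor was set at 3 read pairs, or 6 reads, in that genotype, and the ratio against the floor is given as "at least". The list medians also take 0 reads as 6. Read numbers above 0 but under 6 were kept as they are, so such ratios and the "at least" values cannot be ranked against each other. No ratio is given for the 4262 models with 6 reads or fewer in both genotypes.

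The design has 1 comparison, mp clv3 against WT. It was laid out for values per library, with the authors' own comparison as the last resort, and that last resort was used for the calls. With 1 column per genotype, no test against the spread between replicates could be made, and no gene set test that needs residual degrees of freedom (camera, fry) was run. The calls are those of the authors' deposited table at an FDR under 0.05, and, for the counts per gene list, those calls with at least a 2-fold difference. Whether the FDR takes the spread between replicates into account is not stated. At an FDR under 0.05 it called 8544 models higher and 11896 lower. An exact test of read pairs, which holds counting error only, called 7831 and 10612. By the number of models called, the FDR was no stricter than counting error, so the calls are not a check against replicate spread. In the text, higher and lower refer to mp clv3 relative to WT.

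Before the data were examined, 23 gene lists were fixed by locus identifier. They held 362 genes, of which 359 were in the table, and the listed symbol was found in the RefSeq gene table (TAIR10.1) for 351; the others are named by locus. For each list, the median log2 ratio over members above the floor is given with its percentile among 10000 random lists of the same size matched on expression (50 bins). The percentile describes these columns and treats genes as independent, which members of a pathway are not. Percentiles under 2.5 or over 97.5 are described as standing apart. An exact binomial test of read pairs, adjusted by Benjamini-Hochberg, called 335 of the 369 list memberships, and 335 when adjusted over the list alone, with no list differing in its count; this test compares the reads of the 2 columns, not the genotypes.

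The genes named were chosen by a rule fixed in advance: MP, CLV3, WUS, CLV1, STM, LFY, DRN, ARR7 and ARR15; the 5 higher and the 5 lower called genes with a symbol, an RPKM of at least 5 in the higher genotype and the largest deposited log2 ratio, with zeros at 0.5; and from each list up to 3 called members with the smallest FDR, or the 1 member with the smallest FDR where none was called. Ties at an FDR of 0 were ordered by the size of the ratio, an order the rule did not state. The rule also asked that replicates not overlap between genotypes, which could not be applied with 1 column per genotype. Genes named outside this rule are marked. Of the 81 genes chosen by the rule, 16 overlap another annotated gene, so that part of their reads may belong to the other strand or gene.

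Alternatives were other scalings (TMM from edgeR 4.0.16 and median-of-ratios size factors from DESeq2 1.42.0, in R 4.3.3), other thresholds, filters and pseudocounts, and the exact test of read pairs. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. In a test on simulated data for mp clv3 against WT, read pairs were drawn for 27322 models, with 200 of them changed. The exact test called 83.0% of 94 models changed 2-fold and 91.5% of 106 changed 4-fold, and 95.8% of the intervals held the true ratio. The simulated pairs carried counting error only, which the test and the intervals assume. These figures therefore check the computation and say nothing about the spread between plants or libraries.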

Results

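The transcriptome of inflorescence shoot apices was measured by mRNA sequencing in wild-type Arabidopsis (Col-0) and in a line mutant for both MP and CLV3, with 2 biological replicates per genotype according to the labels. The table has 1 column of read numbers per genotype, and whether it sums both replicates or holds 1 of them is not stated. MP (MONOPTEROS, ARF5) is an auxin response factor, a transcription factor through which auxin acts on organ initiation. CLV3 encodes the signalling peptide that restricts the stem cell population of the shoot meristem. The columns held 103347441 reads in mp clv3 and 101878433 in WT. No reads were listed for 4706 of the 27322 gene models in mp clv3 and for 2984 in WT. All values are the authors' single values per genotype, so no difference has a replicate check, and each 95% interval, given in parentheses after a ratio, covers counting error only. Genes described as called are those with an FDR under 0.05 in the authors' deposited table.

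The targeted genes were examined first. MP (AT1G19850; chromosome 1, 6886669 to 6891404 on the plus strand of TAIR10.1, up to 14 exons) was at 14.5 RPKM in mp clv3 and 46.1 RPKM in WT, 3.18-fold lower in the mutant (95% interval 3.04 to 3.32). CLV3 (AT2G27250; chromosome 2, 11664978 to 11665797 on the minus strand, up to 3 exons) went the other way, at 15.8 RPKM from 1278 reads in mp clv3 and 0.0251 RPKM from 2 reads in WT. The CLV3 ratio was 630-fold, with an interval of 113 to 24919 that is wide because the WT value rests on a single read pair. The positions of the lesions in the transcripts are not given in the sources used here, so the transcript level of neither gene checks its mutation. The annotated span of MP shares 23 bases with AT1G19860 on the opposite strand.

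Across the transcriptome, more genes were lower than higher in mp clv3. The genes named first were ranked by the log2 ratio of the authors' deposited table, in which 0 reads count as 0.5, so the order rests on that value for genes with 0 reads, whose ratios are given here only as lower bounds. The 5 lower genes so chosen had no reads in mp clv3: LCR66 (187 RPKM in WT, at least 1902-fold lower), MS2 (37.1 RPKM, at least 1349-fold), CSLA01 (29.7 RPKM, at least 976-fold), sks18 (26.7 RPKM, at least 909-fold) and ATA1 (50.6 RPKM, at least 773-fold). MS2 encodes a fatty acyl reductase of pollen wall formation. Among the 5 higher genes so chosen, SRO4 (50.1 RPKM in mp clv3), OSM34 (34.1 RPKM), UGT73B4 (2600 reads) and MCT2 (22.9 RPKM) had no reads in WT and were at least 1001-fold, 602-fold, 427-fold and 329-fold higher. GSTF7, a glutathione S-transferase, was at 63.7 RPKM against 0.0424 RPKM from 4 reads in WT, a ratio of 1501 (415 to 12399). UGT73B4 overlaps its same-strand neighbour AT2G15480 in the annotation, which also had more reads in mp clv3 (3503 against 126), and GSTF7 belongs to a family of similar sequences, so their reads can be split between copies. In the authors' deposited table, 8544 models were higher and 11896 lower at an FDR under 0.05, together 74.8% of all models. The exact test of read pairs, which holds counting error only, called fewer (7831 and 10612). The excess of lower models depended on the scaling: under TMM the exact test called 8881 higher and 9496 lower. Among the authors' calls, 2911 were at least 2-fold higher and 5512 lower under TMM. The authors' deposited table held 2692 higher and 5826 lower models with at least a 2-fold difference. With a pseudocount of 5 RPKM these counts were 1161 and 1464, and with an RPKM of at least 1 required in either genotype 2155 and 3635. By counting error alone, the whole interval lay beyond 2-fold for 2013 models higher and 3945 models lower.

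Among genes of the stem cell niche, CLV3, WUS and CLV1 were higher in mp clv3, while the list of stem cell and CLAVATA genes did not stand apart. WUS, the homeodomain factor of the organising centre, was 9.29-fold higher (7.84 to 11.1), at 21.8 against 2.34 RPKM. CLV1, the receptor kinase for the CLV3 peptide, was 2.54-fold higher (2.43 to 2.65). The receptor kinase ERL1 was 2.56-fold higher (2.42 to 2.71), and the CLV1-related kinase BAM2 was 3.73-fold lower (3.53 to 3.94). BAM2 overlaps an annotated opposite-strand gene over 757 bases. Of the 19 listed stem cell and CLAVATA genes, 4 were called at least 2-fold higher, 3 at least 2-fold lower, and 12 did not meet both criteria. The list median was 0.15 on the log2 scale, at percentile 84.3 of matched random lists.

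**Figure D1:**
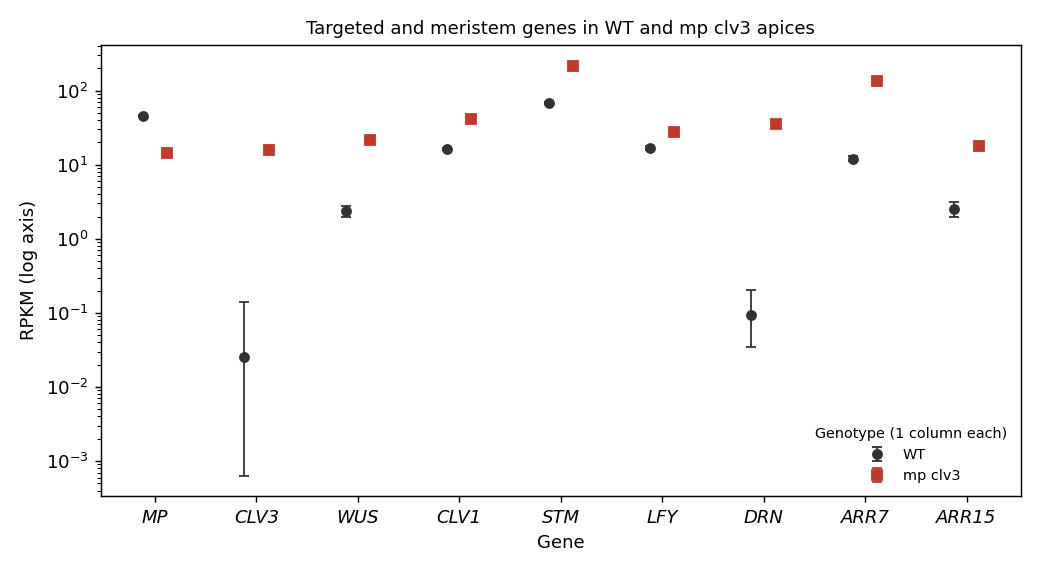
RPKM on a log axis for the targeted genes MP and CLV3 and 7 meristem, organ and cytokinin genes in WT (circles) and mp clv3 (squares), 1 value per genotype, with 95% exact Poisson intervals on read pairs as error bars. MP lies lower in mp clv3 (14.5 against 46.1 RPKM) and the other genes lie higher, with CLV3 and DRN near the detection floor in WT (2 and 12 reads).

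Homeobox genes of the meristem and genes of organ boundaries differed in both directions. STM, a KNOX factor that keeps meristem cells undifferentiated, was 3.16-fold higher (3.05 to 3.26), at 217 against 68.8 RPKM, and the BELL partner gene PNF was 6.41-fold higher (5.88 to 6.98). The BELL gene ATH1 was 8.78-fold lower (7.25 to 10.7). BOP2, which acts in boundary regions and lateral organs, had 2 reads in mp clv3 and 1981 in WT, a ratio of 1005 (180 to 39746), and overlaps an opposite-strand gene over 607 bases. Named after their values were seen, the boundary gene CUC3 was 8.35-fold lower (5.78 to 12.1) and its relative CUC1 was 4.14-fold higher (3.67 to 4.66). Of the 17 measured members of this list, 5 were called at least 2-fold higher and 10 lower, and the median log2 ratio of -1.74 lay at percentile 0.02. With a pseudocount of 5 RPKM the median was -0.31 and the list no longer stood apart, at percentile 3.23.

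Regulators of organ initiation differed in both directions, and YABBY genes of abaxial organ identity were lower. DRN, an AP2-type factor of the meristem and organ primordia, was 378-fold higher (173 to 1031), at 35.7 against 0.0944 RPKM from 12 reads in WT. LFY, the floral meristem identity factor, was higher by 0.70 on the log2 scale (0.59 to 0.81), at 27.4 against 16.9 RPKM. The YABBY genes FIL and YAB3, which mark the abaxial side of young organs, were 77.2-fold (57.5 to 106) and 130-fold (82.1 to 219.8) lower, and YAB2 had 2 reads against 2258. Named after its value was seen, the PLETHORA-type gene AIL7 was higher by 4.64 on the log2 scale (4.48 to 4.81). Of the 20 organ initiation genes, 6 were called at least 2-fold higher and 7 lower, with a median log2 ratio of -0.21 at percentile 22.3 (-0.03 with a pseudocount of 5 RPKM). The polarity list had 3 members called at least 2-fold higher and 9 lower of 15, with a median of -1.26 at percentile 0.02 (-0.75 with a pseudocount of 5 RPKM). Those 3 include PHB, 5.08-fold higher (4.92 to 5.24), and CNA, 3.97-fold higher (3.87 to 4.06), both class III HD-ZIP factors and both named after their values were seen.

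Floral organ identity genes had the lowest median among the lists of developmental regulators. Of 16 measured, 12 were called at least 2-fold lower and 1 higher, and the median log2 ratio of -5.51 (-1.64 with a pseudocount of 5 RPKM) lay below all 10000 random lists. In that median 2 members with 0 reads entered at 6 reads, and with zeros at 0.5 it was -7.63. The petal and stamen gene AP3 and the SEPALLATA genes SEP1 and SEP2 each had 2 reads in mp clv3, against 9839, 6844 and 10236 in WT. Their ratios were 4990 (895 to 197171), 3471 (623 to 137150) and 5192 (931 to 205105), and SEP1 overlaps an opposite-strand gene over 449 bases. The member called at least 2-fold higher was UFO, an F-box protein gene of floral meristems, 10.5-fold higher (8.35 to 13.2) and named after its value was seen. Carpel and ovule genes had 10 of 13 members called at least 2-fold lower, among them CRC, 237-fold lower (130 to 440), and NGA1, at 0 reads and at least 260.0-fold lower. SPT, a bHLH factor of carpel margins, was higher by 2.39 on the log2 scale (2.32 to 2.46). The median of that list was -3.38 at percentile 0.08, and -0.38 at percentile 0.33 with a pseudocount of 5 RPKM.

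Of the 3 lists of older-flower markers, the anther tapetum list stood apart, while the meiosis and pollen lists did not. All 21 anther tapetum genes were called at least 2-fold lower, with a median log2 ratio of -7.61 (-2.40 with a pseudocount of 5 RPKM) below all 10000 random lists. AT5G07230 had 2 reads against 9477, and CYP704B1, a P450 of sporopollenin synthesis, had 3 against 9658. Their ratios were 4807 (862 to 189919) and 3266 (678 to 20231). All 8 meiosis genes were called lower, 5 of them at least 2-fold. Among them were DMC1, 4.65-fold lower (4.12 to 5.23), ASY1, 4.02-fold lower (3.36 to 4.84), and ZYP1a, 2.96-fold lower (2.43 to 3.62) and close in sequence to ZYP1b. The median of the meiosis list was -1.17 at percentile 12.6 (-0.32 with a pseudocount of 5 RPKM). Its matched random lists were themselves lower, with a median of -0.44. Pollen genes had 8 of 11 members at least 2-fold lower and 1 higher, with a median of -1.97 at percentile 3.86. The pollen list did stand apart with a pseudocount of 5 or 1 RPKM (percentiles 1.16 and 0.41) and with an RPKM minimum of 1 (2.23). VGD1 was 12.3-fold lower (8.79 to 17.2) and AT1G49490 was 3.74-fold lower (3.14 to 4.48), while AT2G15880 was 14.0-fold higher (13.4 to 14.7). The tapetum list took 0.00317% of reads in mp clv3 and 0.145% in WT, and the meiosis list 0.00289% and 0.00795%. The pollen list went the other way, with 0.0626% of reads in mp clv3 and 0.00913% in WT. Most of its reads in mp clv3 came from AT2G15880 alone (62226, against 4372 in WT), so this share does not describe the other members.

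**Figure D2:**
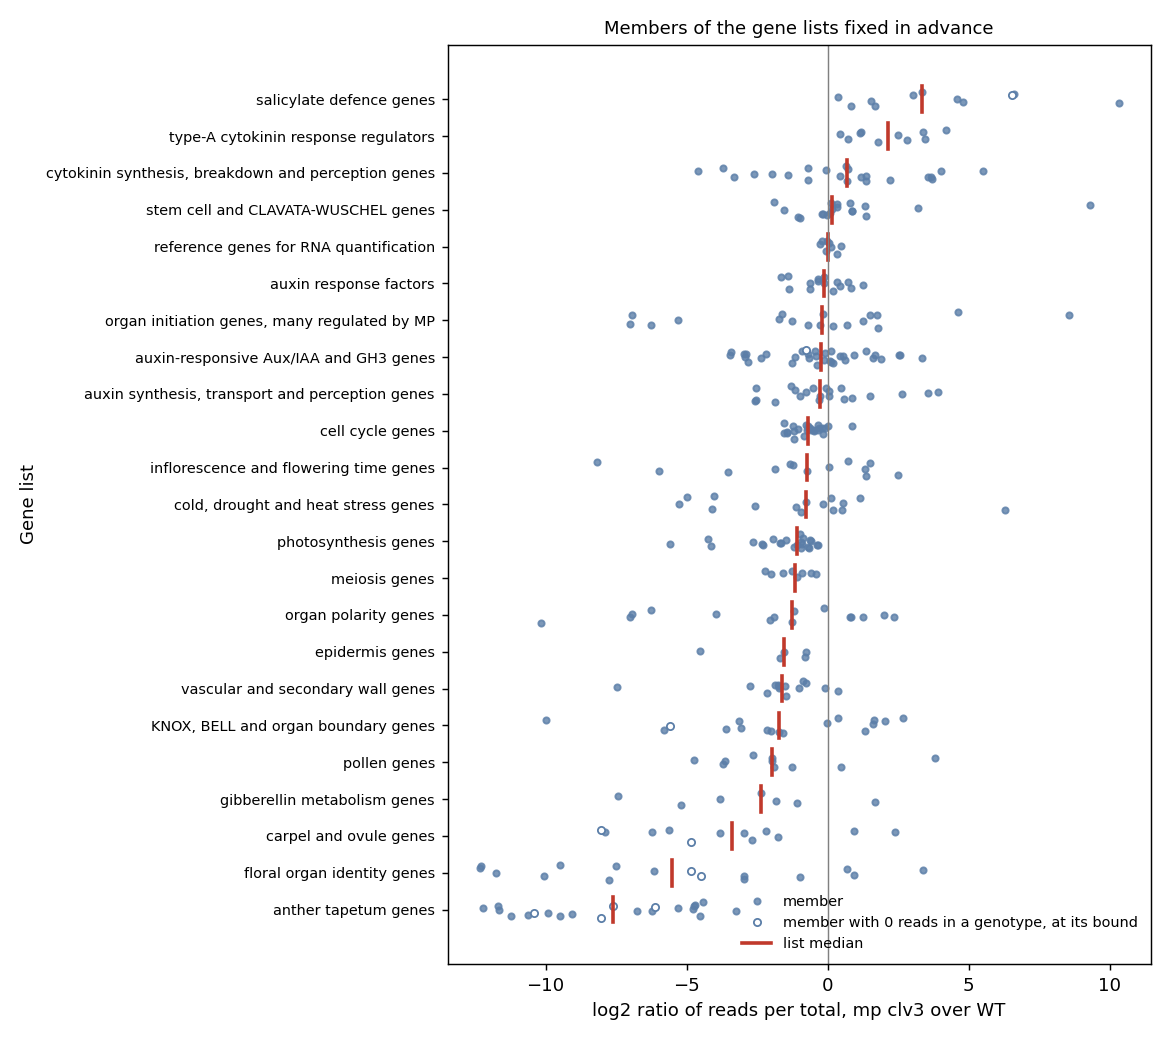
Log2 ratio of reads per total (mp clv3 over WT) for the members of the 23 gene lists fixed in advance, ordered by list median (red bar); open circles are members with 0 reads in a genotype, drawn at the bound set by 6 reads. The anther tapetum list has the lowest median (-7.61), the salicylate defence list the highest (3.35), and the reference genes lie near 0 (0.02). Medians take members with 0 reads at the bound set by 6 reads.

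Flowering regulators differed in both directions. SVP, a MADS-box repressor of flowering, was 5.59-fold higher (5.21 to 5.99). The SQUAMOSA promoter binding genes SPL5 and SPL4 were at log2 ratios of -5.97 (-6.51 to -5.44) and -1.85 (-1.93 to -1.77). SPL5 overlaps AT3G15260 on the opposite strand over 1959 bases, which had 3482 reads in mp clv3 and 2319 in WT. Of 13 list members, 4 were called at least 2-fold higher and 6 lower, with a median log2 ratio of -0.74 at percentile 0.705. With a pseudocount of 5 RPKM the median was -0.37, at percentile 2.66.

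Single auxin genes differed in both directions, and none of the 3 auxin lists stood apart. GH3.6, an auxin-conjugating enzyme gene, was 10.2-fold higher (9.65 to 10.7), and the Aux/IAA repressor genes IAA18 and IAA26 were 5.85-fold (5.58 to 6.12) and 3.75-fold (3.65 to 3.86) higher. GH3.3, named after its value was seen, was 7.53-fold lower (6.20 to 9.22). Of the 35 Aux/IAA and GH3 genes, 7 were called at least 2-fold higher, 11 lower and 17 neither, and their median of -0.24 (-0.03 with a pseudocount of 5 RPKM) lay at percentile 41.7. The auxin synthesis genes YUC4, YUC1 and TAA1 were higher by 3.90 (3.56 to 4.27), 3.58 (3.26 to 3.90) and 2.63 (2.55 to 2.71) on the log2 scale. The full list for synthesis, transport and perception had 4 of 22 members at least 2-fold higher and 6 lower, with a median of -0.26 at percentile 9.9. Among the 15 auxin response factors, MP was among 3 called at least 2-fold lower, ARF19 was 2.42-fold higher (2.28 to 2.57) and ETT was 1.79-fold higher (1.74 to 1.85). The median of the response factors was -0.13 at percentile 28.7.

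Cytokinin response regulators were higher as a group. All 10 type-A ARR genes, which are induced by cytokinin and dampen its signalling, were called higher in the authors' deposited table, 8 of them at least 2-fold. The exact test of read pairs called 9 of the 10. The median log2 ratio of 2.14 (0.94 with a pseudocount of 5 RPKM) lay above all 10000 random lists. ARR5 was 18.5-fold higher (15.9 to 21.6), ARR7 11.1-fold (10.1 to 12.2), ARR15 7.09-fold (5.60 to 9.10) and ARR4 5.62-fold (5.29 to 5.98). ARR7 was at 135 against 12.1 RPKM. Genes of cytokinin synthesis, breakdown and perception had 9 of 24 members at least 2-fold higher and 6 lower, with a median of 0.68 (0.39 with a pseudocount of 5 RPKM) above all random lists. The cytokinin oxidase gene CKX3 was 45.8-fold higher (37.4 to 56.7). Of the cytokinin-activating LOG genes, LOG7 was 16.4-fold higher (13.5 to 20.2) and LOG1 was 23.9-fold lower (18.7 to 30.6). These differences stand beside the lower floral and anther transcripts in mp clv3. Whole apices were measured, so changed regulation and a different tissue make-up cannot be told apart for these or the other lists.

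Gibberellin metabolism genes were lower in 6 of 7 cases at the 2-fold level, with a median log2 ratio of -2.37 at percentile 2.98. Whether the list stood apart depended on the setting: it did with a pseudocount of 1 RPKM (percentile 2.0) and an RPKM minimum of 1 (2.02), and did not with a pseudocount of 0.1 (5.53) or 5 (7.75, median -0.29). GA2OX1, a gibberellin-inactivating oxidase gene, had 8 reads against 1373 and was 174-fold lower (67.7 to 641), and the biosynthetic gene GA20OX2 was 14.0-fold lower (8.69 to 22.8). GA2OX2 was higher by 1.68 on the log2 scale (1.56 to 1.79).

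Cell cycle genes were lower by a small factor. Of 25, 8 were called at least 2-fold lower and none at least 2-fold higher in the authors' deposited table, where 23 were lower and 1 higher at an FDR under 0.05 without the size criterion. The median log2 ratio was -0.69, below all 10000 random lists (-0.43 at percentile 0.14 with a pseudocount of 5 RPKM). The cyclin genes CYCD1;1, CYCB1;2 and CYCD3;3 were 2.89-fold (2.74 to 3.05), 2.68-fold (2.55 to 2.82) and 2.27-fold (2.14 to 2.41) lower.

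Markers of other tissues were lower as well. Photosynthesis genes were all called lower, 12 of 23 at least 2-fold, with a median log2 ratio of -1.08 below all random lists. The Rubisco small subunit genes RBCS2B, RBCS1B and RBCS3B were at log2 ratios of -5.59 (-5.76 to -5.43), -4.24 (-4.34 to -4.14) and -4.12 (-4.16 to -4.08), and are near-identical copies between which reads can be split. Models encoded in the chloroplast took 0.498% of reads in mp clv3 and 1.07% in WT. Epidermis genes were lower in all 5 cases, 3 of them at least 2-fold, with a median of -1.55 at percentile 0.215. The wax synthesis gene CER1 was 22.9-fold lower (21.6 to 24.1), PDF1 3.22-fold (3.16 to 3.28) and FDH 2.93-fold (2.85 to 3.02). Vascular and secondary wall genes had 10 of 15 members at least 2-fold lower, with a median of -1.61 at percentile 0.09 (-0.71 with a pseudocount of 5 RPKM). The laccase gene LAC4 was 6.79-fold lower (5.79 to 7.95), the xylem protease gene XCP2 4.38-fold (4.07 to 4.72) and the phloem sucrose transporter gene SUC2 1.85-fold (1.75 to 1.95).

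Salicylate defence genes were higher as a group. Of 12 listed, 11 were called higher in the authors' deposited table, 9 of them at least 2-fold, and the median log2 ratio of 3.35 (1.28 with a pseudocount of 5 RPKM) lay above all random lists. PR2, a pathogenesis-related glucanase gene, had 23354 reads against 18 and was 1279-fold higher (674 to 2798). PR5 was 28.2-fold higher (19.1 to 43.5), and CBP60G, a regulator of salicylate synthesis, was 23.8-fold higher (19.6 to 29.2). These values stand beside the lower floral, epidermal and photosynthesis transcripts in mp clv3, and a different tissue make-up of the apices was not separated from them. Growth or harvest conditions that may have differed between genotypes were not separated from them either.

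Cold, drought and heat genes were mixed, with 2 of 15 at least 2-fold higher and 6 lower and a median log2 ratio of -0.77 at percentile 1.46 (-0.49 with a pseudocount of 5 RPKM). ADH1, alcohol dehydrogenase, was 77.9-fold higher (73.1 to 83.1), at 1019 against 13.1 RPKM. The cold-regulated genes COR15A and COR15B were 38.9-fold (34.6 to 43.9) and 32.0-fold (28.2 to 36.2) lower; they are similar copies, and COR15B overlaps an opposite-strand gene over 468 bases. None of the 8 reference genes used for RNA quantification differed at least 2-fold. UBQ10 was 1.38-fold higher (1.36 to 1.39), GAPC1 1.09-fold higher (1.07 to 1.11) and ACT2 1.14-fold lower (1.11 to 1.17), and the median of the 8 was 0.02.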

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

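No paired analysis was possible because the deposited table has 1 column per genotype, with no replicate number; for the same reason no library could be left out, and neither DESeq2's test nor any other test against replicate spread could be run. Depth limits the models near the floor of 6 reads, such as CLV3 in WT. The RPKM minimum, the pseudocount of 1, the exact test of read pairs, the other treatments of zeros and all alternatives for the low-oxygen and wounding lists were chosen after the data had been seen. Of 200 alternative values of list medians, 193 kept their sign and their side of the percentile thresholds. Of 26 counts of models, 23 stayed within 1.5 times, and the 4 values for MP and CLV3 kept their direction. None reversed. TMM and median-of-ratios scaling placed the centre of the log2 ratios at -0.09 and -0.10, which raises every ratio by that amount. Such a constant leaves the percentile of a list as it is, so the 50 list medians under these scalings, counted among the 193, say nothing about which lists stand apart. All 23 medians of the fixed lists kept their sign under both, and 6 moved by over 1.5 times. With a pseudocount of 5 RPKM, 1161 models were at least 2-fold higher (2692 without it) and 1464 lower (5826); with an RPKM of at least 1 required in either genotype, 3635 were lower. A pseudocount of 5 moved 17 of the 23 list medians by over 1.5 times and a pseudocount of 1 moved 9, for example tapetum from -7.61 to -2.40, floral identity from -5.51 to -1.64, carpel from -3.38 to -0.38 and type-A ARR genes from 2.14 to 0.94 with a pseudocount of 5. These counts and medians shrink because models of low level are compressed or removed. A pseudocount of 5 also moved the boundary list (median -0.31) and the flowering list (-0.37) to where they no longer stood apart, and the pollen list (-0.39) to where it did. The pollen list also stood apart with a pseudocount of 1 (-1.18) or the RPKM minimum (-2.29), and the gibberellin list with a pseudocount of 1 (-1.05) or the RPKM minimum (-2.82); the cause was not tested. The exact test of read pairs called 7831 models higher and 10612 lower in place of 8544 and 11896, and 8881 and 9496 under TMM. Leaving zeros at 0.5 moved the floral identity median to -7.63 and the tapetum median to -9.48.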

Other observations

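All patterns in this part were noticed in the data, and the tests of meristem share, neighbouring models and linked segments were chosen after their results could be seen; those on the low-oxygen genes not seen before and on the wounding list were set before their values were computed. A group of genes induced by low oxygen, listed from general knowledge after some members had been seen, was higher in mp clv3. All 30 were called higher in the authors' deposited table, 27 of them at least 2-fold, with a median log2 ratio of 4.49. The exact test of read pairs called 29 of the 30. PDC1, pyruvate decarboxylase of ethanolic fermentation, was at a log2 ratio of 7.13 (95% interval 6.93 to 7.33), the haemoglobin gene HB1 at 8.34 (7.94 to 8.76) and the low-oxygen transcription factor gene HRE2 at 8.15 (7.35 to 8.97). The sucrose synthase genes SUS1 and SUS4 were at 4.84 and 5.94, while HRE1 was at 0.35 (-0.05 to 0.74). The list took 1.13% of reads in mp clv3 and 0.052% in WT. It includes AT2G15880, the pollen list member called at least 2-fold higher in mp clv3, which was among the members already seen.

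Gene families named in the RefSeq annotation gave further values. Over all 27322 models, 2692 were called at least 2-fold higher and 5826 lower. Of 72 WRKY transcription factor models, 31 were called at least 2-fold higher and 12 lower, with a median log2 ratio of 0.99. Of 155 disease resistance protein models, 53 were at least 2-fold higher and 17 lower (median 0.67), and of 45 glutathione S-transferase models 23 were higher and 6 lower (median 1.37). Invertase and pectin methylesterase inhibitors had 48 of 111 models at least 2-fold lower and 5 higher, lipid transfer proteins 44 of 139 lower and 15 higher, and UDP-glycosyltransferases 31 of 131 higher and 30 lower. Pectin lyases had 41 of 103 models at least 2-fold lower and 6 higher, and GDSL lipases 41 of 96 lower and 9 higher. Histones had a median of -0.53 at percentile 0.56 of random lists, with 8 of 48 at least 2-fold lower and 0 higher. Ribosomal proteins had a median of -0.13, at the 42.5th percentile of random lists. The WRKY, disease resistance and glutathione S-transferase groups lay at percentile 100, and the UDP-glycosyltransferases at 97.3. The inhibitors lay at percentile 0.03, and the lipid transfer, pectin lyase and GDSL lipase groups at 0.

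For the low-oxygen pattern, the tables argue against a list carried by the members already seen. The 24 members not seen before had a median of 4.22 and lay at percentile 100 of matched random lists. Damage or touch at collection stays open: a list of 18 wounding, jasmonate and touch genes also lay at percentile 100 with a median of 2.15, with 12 members called at least 2-fold higher and 3 lower. WRKY40 was at 7.91 and TCH3 at 4.92, while LOX2 was at -2.41, VSP2 at -2.07, VSP1 at -1.28 and TCH2 at -0.79. The list took 0.434% of reads in mp clv3 against 0.595% in WT. VSP1 alone held most of the list's reads in WT (419532, against 175622 in mp clv3), so this share does not describe the other members. Low oxygen inside the mutant apices is a candidate explanation that stays open, since oxygen was not among the measurements and it was not tested. Growth or harvest conditions that differed between genotypes may also account for both lists. The same holds for the salicylate list and the WRKY, disease resistance and glutathione S-transferase groups. Conditions that went with genotype cannot be separated from it here, and separate columns per replicate would not by themselves separate them.

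CLV3 had 2 reads in WT apices that held 294 reads of WUS and 9556 of STM. A smaller meristem share in the WT tissue may lower every meristem gene. The upper bound for WUS (3.47 on the log2 scale) lay below the lower bound for CLV3 (6.82), which argues against a single factor for WUS and CLV3. These bounds hold counting error only. DRN, with 4602 reads in mp clv3 and 12 in WT, had an interval (7.44 to 10.0) that overlaps that of CLV3 (6.82 to 14.6). Reads spilling over from neighbouring models can only add reads, so they cannot account for the low number in WT. As a source of the 1278 CLV3 reads in mp clv3, spill-over is argued against by the neighbours' values. The higher upper bound of their ratios was 0.68, from AT2G27260, which had 4507 reads in mp clv3 and 2955 in WT. AT2G27240 had 0 reads in mp clv3 against 488 in WT, at least 82.5-fold lower and opposite in direction to CLV3. A change in CLV3 transcription or stem cell number in the mutant, and how reads were assigned to the CLV3 model in WT, stay open and were not tested.

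A segment of another accession linked to either mutation could change its neighbours together. In windows of 100 gene models, 33 around MP and 40 around CLV3 were called at least 2-fold different, against a median of 36 over 22264 windows. The higher of the 2 percentiles was 76.7, which gives no sign of such a segment at this window size. With 36 of 100 models different in the median window, a segment that changed only a few genes would not stand out. Such a segment therefore stays open. AT2G27240, next to CLV3, is among the genes that differed.

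The 3 near-identical Rubisco small subunit genes RBCS1B, RBCS2B and RBCS3B, summed, were 19.3-fold lower in mp clv3, RBCS1A was 3.21-fold lower, and the sum of all 4 was 4.56-fold lower. There were 1170 models with no reads in mp clv3 and reads above the floor in WT, and 165 of the opposite kind.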
